A study of Homo sapiens with 6 samples.

How the data were processed

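Poly(A) RNA from 6 samples of RKO cells, labelled shControl or shRPLP0P2 with replicates 1 to 3, was sequenced as paired-end reads on an Illumina NovaSeq instrument, per the labels' protocols. Per those protocols, RNA with an integrity number above a set minimum went through repeated oligo(dT) selection, fragmentation and a dUTP step that marks the strand. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2, edgeR and the build GRCh38, without roles or order. The counting program, and whether it used the strand, are not given in the sources used here, so genes with overlapping, antisense or near-identical partners carry uncertain counts.

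The authors deposited one table of 60612 Ensembl genes with 6 columns of raw counts and 6 columns of FPKM, per the file headers. The counts are whole numbers, not normalised. The deposited FPKM values are proportional to count over length within each library, and every value with a count of 0 is listed at an FPKM of 0.0001. Libraries were grouped by their titles. The genotype entries of the knockdown samples spell the gene differently and carry rising numbers, which titles and descriptions do not, and they were not used. Of the gene identifiers, 58394 were found in GENCODE v29, which gave gene classes, transcript lengths and GC content, and 99.98% of them overlapped the position in the table. Coordinates are those of the table, in GRCh38.

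Total counts ranged from 47612346 to 72274217 per library. Pairs of libraries within a group differed by far more than counting noise (chi-square per degree of freedom 44.6 to 70.8), so none was counted as a duplicate. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts of all 6 libraries, with filterByExpr, TMM normalisation and no replicate block. It was two-sided, with a threshold of 0.05 on the Benjamini-Hochberg adjusted p. The design written before the data were examined provided for this test if the table held counts, with limma on log2(FPKM + 1) of genes with a mean FPKM of at least 1 as an alternative. SE values are the fold change over the square root of the quasi-likelihood F statistic. CPM values are counts scaled to a common total by the TMM-scaled library size.

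The gene lists, 50 in all, were fixed before the data were examined, and the 46 with at least 5 tested members went through camera (limma 3.58.1) with a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists. A camera test with an estimated correlation, camera on ranks and fry stand beside it. Genes were named by a rule fixed at the same time. It takes RPLP0P2 and RPLP0, and the 12 genes with the largest log2 fold change in each direction among those past the threshold. Their 3 values in one group must lie on one side of the other 3, the higher group must have a mean of at least 2 CPM, and the symbol must not be a clone or Ensembl name. It also takes the 2 to 4 members with the smallest p in each list described, and genes past the threshold within 500 kb of RPLP0P2. RPLP0P6, MALAT1, NEAT1, RMRP in its list, RNA5-8SN1 to RNA5-8SN3 and the 4 ribosomal DNA genes were chosen after their values were seen. Some genes that the rule takes are not reported here. Folds against a group with no counts used a floor of 3 counts over the group.

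The procedure was tested on simulated counts of 16722 genes with the means and library sizes of this comparison and 200 genes changed. It recovered 19.4% of the genes changed 1.5-fold, 40.3% of those changed 2-fold and 81.8% of those changed 4-fold. False calls were 7 among 101. The changed genes were a far smaller share than the calls in these data, which makes the adjusted threshold harder to pass in the simulation. It held no trend with length and GC content and no shift of ribosomal DNA counts, so false calls from these were not tested. On simulated lists over 16739 genes, 1 of 1 shifted lists was recovered and 0 of 19 others was called. The genes of these lists were picked at random and varied independently. The simulation therefore cannot show how often camera with the preset correlation calls lists of genes that vary together.

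Alternatives covered filters, normalisations, the test (DESeq2 1.42.0, limma on FPKM with other pseudocounts, filters and scalings), gene classes, thresholds, a replicate block and leaving out each library. Scaling by total counts alone, leaving out the ribosomal DNA or mitochondrial genes, and offsets for transcript length and GC content were chosen after seeing the data. The offsets are natural splines with 4 degrees of freedom in log2 length and in GC content of each gene's longest annotated transcript. They were fitted per library over genes with a mean log2 CPM above 1. Figures were drawn with matplotlib.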

Results

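RNA from RKO cells, a human colon carcinoma line, was sequenced after short hairpin RNA knockdown of RPLP0P2. This transcribed pseudogene is a copy of the ribosomal protein gene RPLP0, and the question was what it does in colon cancer cells. The series holds 6 poly(A)-selected libraries, 3 labelled shControl and 3 labelled shRPLP0P2. Total gene counts were 72274217, 69685295 and 56640840 in control replicates 1 to 3. They were 50084022, 47612346 and 58603137 in knockdown replicates 1 to 3. The labels do not say whether the numbers mark separate cultures or separate hairpins. The p-values therefore measure only the spread between these libraries, which may be technical.

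RPLP0P2, the targeted transcript, was at 45.9 ± 0.760 TMM-normalised CPM (gene counts scaled to a common library total) in the control libraries and 39.9 ± 3.29 in the knockdown libraries (SD, n = 3 each). The difference was -13.1% (95% confidence interval -23.7% to -0.896%). The log2 fold change was -0.20 (SE 0.08), and it did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.0970). All 3 knockdown libraries lay below all 3 control libraries, at 39.8, 43.2 and 36.7 CPM against 46.7, 45.7 and 45.3 CPM. The two-sided exact permutation test gave p = 0.1, the smallest it can give for 3 against 3. RPLP0P2 (ENSG00000243742) lies on the plus strand of chromosome 11, from 61615036 to 61639449 in GRCh38. The retrocopy itself is the single exon of one annotated transcript, from 61636680 to 61637640. Among the spliced transcripts, only that with the exon from 61636585 to 61639449 covers it. The others lie wholly upstream of it, and the counts of the gene do not tell these transcripts apart. RPLP0, the parent gene and a component of the large ribosomal subunit, was at 2006 ± 18.6 CPM in the controls and 2606 ± 806 CPM in the knockdown. It did not pass (log2 fold change 0.38, adjusted p = 0.200). RPLP0P6, another retrocopy, was at 203 ± 9.74 and 258 ± 49.5 CPM and did not pass either (log2 fold change 0.35, adjusted p = 0.103). In the FPKM values as deposited, RPLP0P2 was at 10.8 ± 0.196 in the controls and 8.05 ± 0.743 in the knockdown, a difference of -25.5%. On that scale it passed in limma (log2 fold change -0.39 on the log2(FPKM + 1) scale, adjusted p = 0.00608). It also passed in edgeR without knockdown replicate 2 (log2 fold change -0.27, adjusted p = 0.0408). In edgeR with offsets for transcript length and GC content the difference was smaller and did not pass (log2 fold change -0.082, adjusted p = 0.426). Those offsets took the longest annotated transcript of the gene, not the shorter one of the retrocopy.

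**Figure D1:**
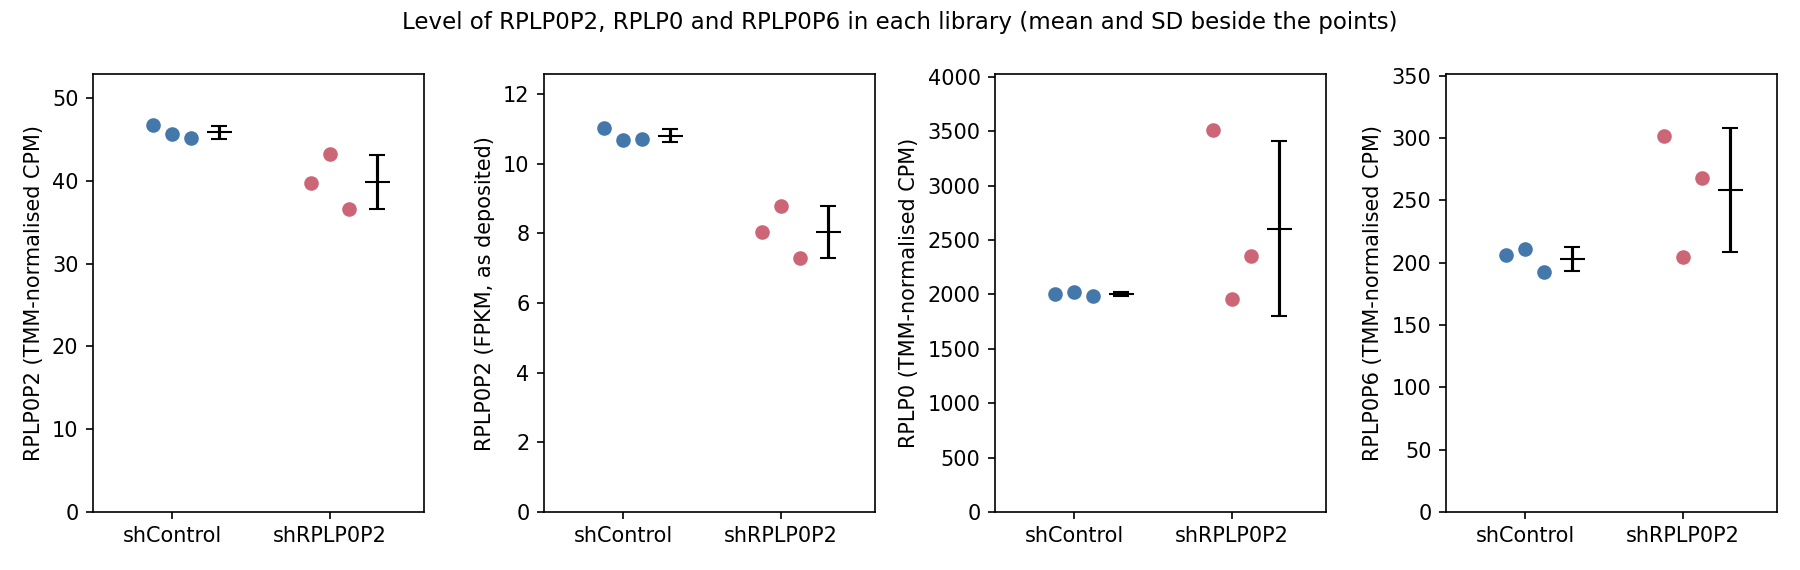
Level of RPLP0P2 in TMM-normalised CPM and in FPKM, and of RPLP0 and RPLP0P6 in TMM-normalised CPM, in each of the 6 libraries (points), with the group mean and SD beside them (n = 3); every vertical axis starts at 0. RPLP0P2 was lower in every knockdown library than in every control library, by 13.1% in CPM means, while RPLP0 ranged from 1955 to 3508 CPM among the knockdown libraries.

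Knockdown and control libraries differed at 5688 of 17375 tested genes, with 2773 higher and 2915 lower in the knockdown. Among the genes with the largest rise were TREM1, a receptor known from myeloid cells, which went from 0.0964 to 7.19 CPM (log2 fold change 6.22). OLAH, a thioesterase that releases fatty acids from fatty acid synthase, went from 0.744 to 22.6 CPM (4.92). The gene SPX, which encodes the peptide hormone spexin, rose (5.57), as did H1-4, a linker histone (4.60), and CLDN1, a tight junction protein (4.34). Among the genes with the largest fall, SLC5A3, the myo-inositol transporter, went from 205 ± 3.55 to 20.9 ± 2.52 CPM (log2 fold change -3.29, SE 0.10, adjusted p = 1.71e-05). MFSD2B, a sphingosine-1-phosphate transporter, fell from 6.0 to 0.0312 CPM (-7.37). Also lower were NPIPB13 (-3.76), ADAT3, a subunit of a tRNA adenosine deaminase (-2.77), YPEL2 (-2.67) and GPR78 (-2.62). C1GALT1C1, the chaperone of an O-glycan galactosyltransferase (-2.59), ZNF114 (-2.48), CRAMP1 (-2.41) and CCDC180 (-2.40) fell too. GLI1, a transcription factor of Hedgehog signalling, fell by 2.33 on the log2 scale. NPIPB13 belongs to a family of near-identical copies, so its counts are uncertain. KBTBD11-OT1 had no counts in any control library and 0.433, 24.1 and 2.28 CPM in the knockdown libraries. Their mean was at least 644-fold higher than the floor of 3 counts over the control group, and without knockdown replicate 2 at least 97.8-fold.

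Of the calls, 601 higher and 706 lower genes changed at least 2-fold. The 3 knockdown values lay wholly on one side of the 3 control values for 8510 tested genes (49.0%), where chance gives 10% for 3 against 3. The balance of higher and lower calls moved with the scaling of the libraries. Scaled by total counts alone, edgeR called 1443 higher and 5010 lower, and limma on the deposited FPKM called 1399 and 4314. Rescaled to TPM, limma called 621 and 7380. The median of all genes moved to -0.25, -0.18 and -0.44 on these scales, from -0.0059.

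Leaving out 1 library could end the calls of 6 of the genes named here. CLDN1 kept its call only without control replicate 1, with adjusted p = 0.0568 to 0.0913 where it was lost. C1GALT1C1 kept its call only without control replicate 2 (0.0731 to 0.0847 where it was lost). Its log2 fold change where lost was -2.22 to -2.69, against -2.59 with all libraries. C1GALT1C1 was at 3.91 CPM in control replicate 2, 26.2 and 28.6 in the other controls and at most 3.69 in the knockdown. KBTBD11-OT1 (0.0564 to 0.0748) and GPR78 (0.0695 to 0.132) lost their calls without any 1 control library or knockdown replicate 3. ZNF114 lost its call without any 1 knockdown library (0.0794 to 0.0974), and NPIPB13 without control replicate 1 (0.0573). Fold changes of genes with few counts moved when 1 library was left out. Without control replicate 3, ZNF114 was at -1.25, SPX at 7.32 and H1-4 at 6.26. Without control replicate 1, SPX was at 4.95, and CLDN1 had 0 control counts and was at least 95.6-fold higher than the floor. Without knockdown replicate 1, GPR78 was at -3.50 and NPIPB13 at -4.48. Leaving out knockdown replicate 2 put ADAT3 at -3.48. Leaving out knockdown replicate 3 put NPIPB13 at -3.14, and left MFSD2B with 0 knockdown counts, at least 180.1-fold lower by the same floor.

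Counts at the ribosomal DNA repeats and of the 8 RNAs of a list of nuclear-retained and non-polyadenylated RNAs were higher in all 3 knockdown libraries than in any control library. The 4 non-coding genes annotated on the minus strand of the ribosomal DNA repeats of chromosome 21 took 0.0260 ± 0.00344% of all counts in the controls and 9.05 ± 0.656% in the knockdown (SD, n = 3 each). Their log2 fold changes ran from 8.25 to 8.77. They lie 1266 to 1272 bp from the 5.8S ribosomal RNA genes and on the opposite strand. Whether counting used the strand is not given in the sources used here, so their counts may be of ribosomal RNA or of RNA antisense to it. Of the 5.8S genes, RNA5-8SN1, RNA5-8SN2 and RNA5-8SN3 were higher by 3.75, 4.01 and 3.87 on the log2 scale. All 8 measured members of that list rose, all 8 also adjusted over the list alone. Their median log2 fold change was 3.64 (camera adjusted p = 1.52e-07, adjusted p = 0.162 with an estimated correlation). They include RPPH1, the RNA of ribonuclease P (6.04), and the signal recognition particle RNAs RN7SL2 (5.00) and RN7SL1 (4.44). RMRP, the RNA of ribonuclease MRP (4.14), and MALAT1, a nuclear-retained long non-coding RNA (3.14), rose with them. So did RN7SK, a regulator of transcription elongation (1.86), and NEAT1, the scaffold of paraspeckles (1.77). RN7SL3 (4.41) and the copy RN7SL4P (5.00) rose as well. Near-identical copies make the counts of single 7SL and ribosomal DNA genes uncertain. Of 25 measured replication-dependent histone genes, H4C12 (2.07), H1-4 (4.60), H2BC9 (0.96) and H2AC13 (0.95) rose and 0 fell. The list did not pass (median 0.27, adjusted p = 0.117), and did in 7 of 33 alternatives (adjusted p = 1.10e-05 to 0.843 over all). Of 51 small nucleolar RNAs 0 rose and 2 fell (median -0.31), of 10 small nuclear RNAs, with RN7SK among them, 2 rose and 0 fell, and of 4 small Cajal body RNAs 0 passed. The libraries of each group carry the difference throughout, so every gene group described here changed together with it.

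**Figure D2:**
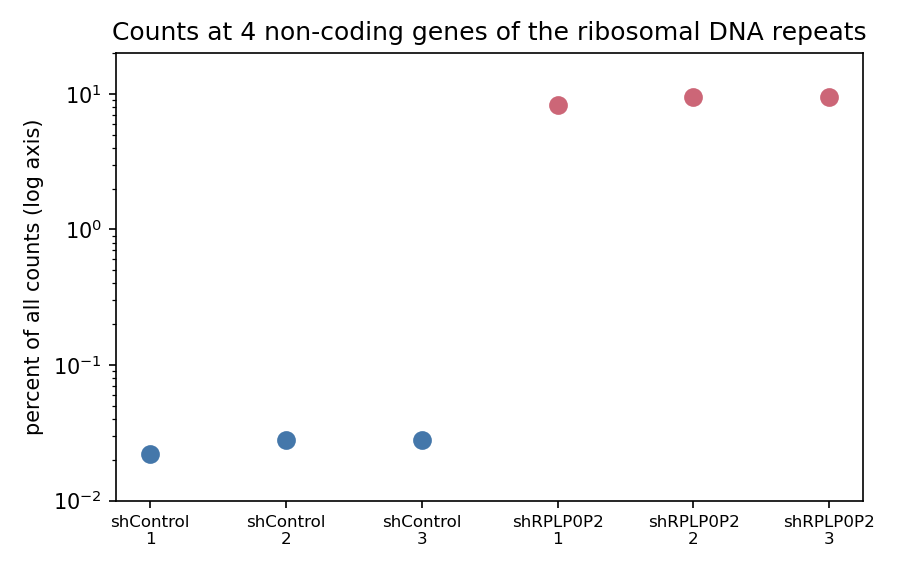
Percent of all counts (log axis) taken by 4 non-coding genes of the ribosomal DNA repeats in each of the 6 libraries, 1 point per library. The 3 control libraries lie between 0.0220% and 0.0282% and the 3 knockdown libraries between 8.29% and 9.44%.

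Of the 46 gene lists with enough measured members, 13 passed camera, 8 up and 5 down. ATF4 and amino acid response genes rose the most among lists of protein-coding genes: 26 of 33 measured members rose, 3 fell and 4 did not pass, and 26 and 3 did so adjusted over the list alone. The median log2 fold change was 0.95 (adjusted p = 8.97e-14, adjusted p = 0.0528 with an estimated correlation). ASNS, asparagine synthetase, went from 168 ± 4.94 to 893 ± 57.9 CPM (log2 fold change 2.41). CTH, which makes cysteine from cystathionine, rose by 2.61, MTHFD2, a mitochondrial folate enzyme, by 1.67 and SARS1, the seryl-tRNA synthetase, by 1.66. Proteasome subunits rose in 25 of 31 members and fell in 0 (with 27 and 0 adjusted over the list alone). The median was 0.57 (adjusted p = 8.97e-14, adjusted p = 0.0528 with an estimated correlation). PSMD14 (1.33), PSMD7 (1.24), PSMC4 (1.07) and PSMA5 (0.98) were among them. G2/M and mitosis genes rose in 27 of 36 members and fell in 1 (with 30 and 1 adjusted over the list alone). The median was 0.54 (adjusted p = 9.17e-11, adjusted p = 0.0528 with an estimated correlation). UBE2C (1.16), CCNB1, cyclin B1 (1.01), TPX2 (1.01) and KIF2C (1.00) rose near a doubling. Genes of G1/S and DNA replication did not pass as a list, with 6 of 36 higher and 10 lower (adjusted p = 0.595).

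Nuclear-encoded respiratory chain genes rose in 46 of 68 members and fell in 1 (with 58 and 1 adjusted over the list alone). The median was 0.51 (adjusted p = 8.97e-14, adjusted p = 0.341 with an estimated correlation). Examples are the complex I subunits NDUFA13 (1.02), NDUFS4 (0.98) and NDUFA9 (0.63) and the ATP synthase subunit ATP5MG (0.94). The mitochondrially encoded genes did not pass as a list, with 3 of 13 higher and 1 lower (median 0.06, adjusted p = 0.295). That list passed as lower with quantile normalization (-0.63, adjusted p = 1.46e-06) and with length and GC offsets (-0.37, adjusted p = 0.0230), and as higher without knockdown replicate 1 (0.14, adjusted p = 0.0130). Cytosolic ribosomal protein genes rose in 37 of 79 members and fell in 0 (with 43 and 0 adjusted over the list alone). The median was 0.34 (adjusted p = 1.70e-09, adjusted p = 0.558 with an estimated correlation), although it was -0.18 on the TPM scale and -0.065 with quantile normalization, where the list lost its call (adjusted p = 0.182 and 0.0753). Relative to the median of all genes it was 0.26 on the TPM scale. RPL36 (0.74), RPL24 (0.50), RPL21 (0.45) and RPS24 (0.39) were higher, RPS24 turning with quantile normalization (-0.00033) and RPS24 (-0.12), RPL21 (-0.055) and RPL24 (-0.012) on the TPM scale. There they lay 0.32, 0.38 and 0.43 above the median of all genes. Translation factors rose in 15 of 36 members and fell in 4 (with 16 and 5 adjusted over the list alone). The median was 0.22 (adjusted p = 0.0127, adjusted p = 0.230 with an estimated correlation), although it was -0.020 on the FPKM scale, -0.022 with total counts, -0.11 with quantile normalization and -0.30 on the TPM scale. Relative to the median of all genes it was 0.16, 0.23, -0.097 and 0.14. The list lost its call with total counts (adjusted p = 0.117) and in limma on FPKM (0.0520 to 0.701) except with median-of-ratios scaling (0.0479). EIF4EBP1, a repressor of cap-dependent translation (1.96), EIF3D (0.91), EIF1AX (0.75) and EIF2S2 (0.68) rose. NF-kB and inflammatory cytokine genes rose in 12 of 25 members and fell in 2 (with 14 and 2 adjusted over the list alone). The median was 0.50 (adjusted p = 0.00833, adjusted p = 0.168 with an estimated correlation), although it was -0.027 on the TPM scale. There it lay 0.41 above the median of all genes and passed (adjusted p = 0.00259), and the call was lost in limma from an FPKM of 5 (0.129). The chemokines CCL20 (2.75) and CXCL8 (1.79) and the adhesion molecule ICAM1 (0.69) rose, and the cytokine IL11 fell (-1.49).

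Heat shock genes fell in 15 of 21 members and rose in 1 (with 16 and 1 adjusted over the list alone). The median was -0.41 (adjusted p = 1.97e-07, adjusted p = 0.0528 with an estimated correlation). The inducible chaperone gene HSPA1B went from 304 ± 7.61 to 87.8 ± 6.44 CPM (log2 fold change -1.79). Its near-identical copy HSPA1A went from 139 ± 5.55 to 40.8 ± 1.55 CPM (-1.77), and the split of counts between them is uncertain. BAG3, a co-chaperone, fell by 1.13 on the log2 scale, and HSPA8, the constitutive HSP70, fell from 2027 to 1016 CPM. Cholesterol synthesis and uptake genes fell in 14 of 25 members and rose in 1 (with 17 and 1 adjusted over the list alone). The median was -0.50 (adjusted p = 5.99e-06, adjusted p = 0.0528 with an estimated correlation). The enzymes DHCR7 (-1.45), LSS (-1.20) and SQLE (-0.96) and their transcription factor SREBF2 (-0.71) fell. Notch pathway genes fell in 7 of 14 members and rose in 2 (with 7 and 2 adjusted over the list alone). The median was -0.74 (adjusted p = 0.0153, adjusted p = 0.217 with an estimated correlation). The receptors NOTCH1 (-2.18) and NOTCH2 (-1.18), the ligand JAG2 (-1.02) and the glycosyltransferase LFNG (-3.74) fell. The Notch list lost its call with total counts (adjusted p = 0.0910) and in limma on FPKM (0.0722 to 0.499) except with no filter, and was not tested there from an FPKM of 5. DNA methylation and chromatin enzymes fell in 14 of 31 members and rose in 3 (with 16 and 4 adjusted over the list alone). The median was -0.25 (adjusted p = 0.00635, adjusted p = 0.551 with an estimated correlation), and the call was lost with quantile normalization (0.0839) and in limma from an FPKM of 5 (0.129). KMT2D (-1.55) and CREBBP (-1.23) fell, and EZH2, the methyltransferase of Polycomb, rose (0.50). On the TPM scale EZH2 was at -0.0072, which is 0.43 above the median of all genes. YAP/TAZ targets fell in 10 of 22 members and rose in 1 (with 12 and 1 adjusted over the list alone). The median was -0.28 (adjusted p = 0.0313, adjusted p = 0.398 with an estimated correlation). AJUBA (-1.25), CCN1 (-1.24), ASAP1 (-0.94) and TEAD1 (-0.89) fell.

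**Figure D3:**
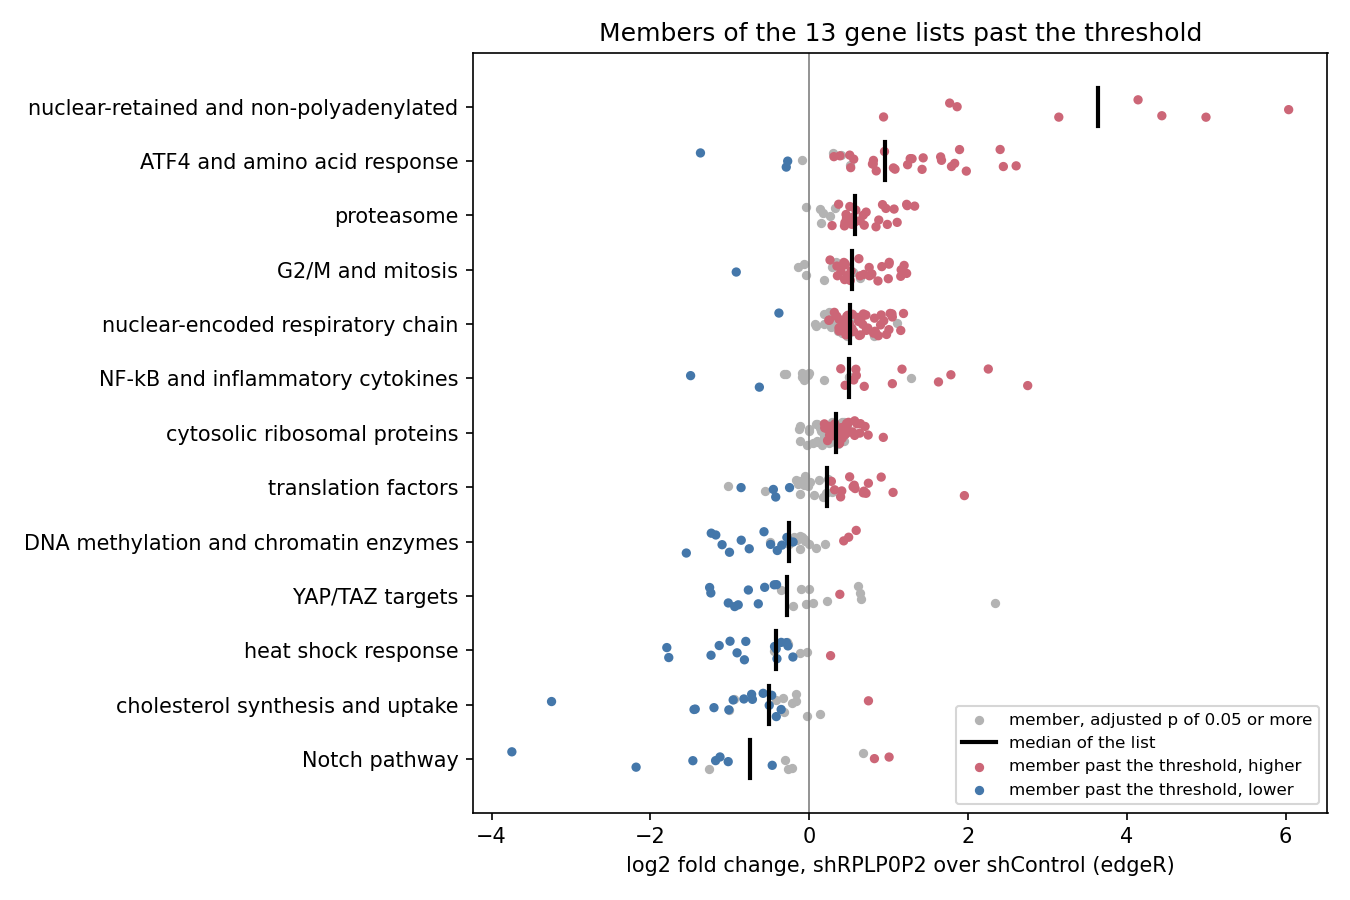
Log2 fold change (knockdown over control) of each measured member of the 13 gene lists past the threshold, with red points for members higher and blue points for members lower at an adjusted p under 0.05, grey points for the rest, and a black bar at each list's median. Medians run from -0.74 for the Notch pathway to 3.64 for nuclear-retained and non-polyadenylated RNAs, with the median of cytosolic ribosomal proteins and of translation factors turning below 0 on the TPM scale and with quantile normalization, and that of NF-kB genes on the TPM scale, where the median of all genes was -0.44.

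None of the 13 lists passed with an estimated correlation. With offsets that remove each library's trend with transcript length and GC content, ATF4 and amino acid response genes (adjusted p = 0.0306) and proteasome subunits (0.0497) did. With these offsets and the preset correlation, respiratory chain genes kept their call with a smaller median of 0.25 and 27 of 68 members higher (adjusted p = 1.23e-07). Cytosolic ribosomal proteins (adjusted p = 0.179), chromatin enzymes (0.673), the Notch pathway (0.0917) and YAP/TAZ targets (0.652) lost their calls. YAP/TAZ targets also did so without control replicate 1, control replicate 3 or knockdown replicate 1 (0.0549 to 0.0612), among protein-coding genes alone (0.0683), with the replicate block (0.0520) and on ranks (0.0561).

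Lists that did not pass in camera include p53 targets, with 5 of 30 members higher and 6 lower (adjusted p = 0.918), and genes of the epithelial-mesenchymal transition, with 1 of 18 higher and 2 lower (adjusted p = 0.980). WNT targets had 1 of 14 higher and 3 lower (adjusted p = 0.291), and the interferon response genes, which short double-stranded RNA can induce, 12 of 35 higher and 4 lower (adjusted p = 0.123). Glycolysis genes had 3 of 22 higher and 3 lower (median -0.0080, mean -0.055, camera direction up, adjusted p = 0.921), and passed as lower in limma on FPKM with no filter (adjusted p = 0.0244) and with quantile normalization (0.0205). TGF-beta and SMAD targets had 1 of 21 higher and 9 lower (median -0.52, adjusted p = 0.0680), and passed in 10 of 34 alternatives (adjusted p = 4.32e-06 to 0.517 over all). These were without control replicate 3 (0.0415), without knockdown replicate 2 (0.0353), edgeR with no filter on counts, both fry tests and 5 of the limma fits on FPKM. Markers of other cell types were scarce: 7 leukocyte markers were measured, 1 of them higher (adjusted p = 0.918). The 3 fibroblast, 2 endothelial and 4 neuronal markers measured were too few to test, and 1 neuronal marker was lower.

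Around the locus, 5 of the 26 tested genes within 500 kb of RPLP0P2 passed the threshold, a share (19.2%) that did not differ from that of other tested genes in Fisher's exact test (two-sided, p = 0.208). MYRF, a membrane-bound transcription factor, was lower (log2 fold change -1.30), as were RAB3IL1 (-0.98), CYB561A3 (-0.85) and DAGLA, a diacylglycerol lipase 40.9 kb away (-0.67), and TMEM258, a subunit of the oligosaccharyltransferase, was higher (0.98). Of 2 tested genes within 100 kb 1 passed, and of 42 within 1 Mb 15 passed (Fisher's exact p = 0.548 and 0.742).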

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

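The scaling by total counts, the fits without ribosomal DNA or mitochondrial genes and the length and GC offsets were chosen after seeing the data. Limma on FPKM as such stood in the design written before, not among its listed alternatives. Where no cause is named the cause was not tested. RPLP0P2 was lower under all alternatives run, from -0.68 on the TPM scale to -0.08 with length and GC offsets. It was at -0.27 to -0.14 with 1 library left out. It stayed short of the threshold in edgeR and DESeq2 fits with TMM or median-of-ratios scaling on all 6 libraries. It passed without knockdown replicate 2 (-0.27, adjusted p = 0.0408), with total counts (-0.45), with quantile normalization (-0.23), on the TPM scale (-0.68) and in limma on FPKM (-0.39, also without a trend, with robust variances and with other filters). It also passed there with pseudocounts of 0.1 and 0.01 (-0.42 and -0.43) and with array weights (-0.46). Adjusted p over these ran from 0.000617 to 0.0408, and over all alternatives to 0.440. The ratio of mean FPKM was -0.43. Total counts and FPKM share a per-million scale on which the median of all genes was -0.25 and -0.18.

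Calls numbered 2773 higher and 2915 lower, and leaving out 1 library gave 1978 to 2614 higher and 2129 to 2793 lower. By construction, an adjusted p under 0.01 left 1524 and 1723, and a 2-fold minimum 601 and 706. DESeq2 called 3305 and 3258, which included 99.9% of the calls. The split moved with total counts (1443 and 5010), TPM (621 and 7380) and limma on FPKM (1399 and 4314). There, 1393 and 1392 genes were higher with the smaller pseudocounts, 1279 with no filter, 1002 from an FPKM of 5, 1386 without a trend and 1385 with robust variances. An FPKM minimum of 0.1 gave 1452 and 4758, and array weights 1659 and 4788. The split stayed near even with TMM on FPKM (2455 and 2740). Without the ribosomal DNA genes 99.1% of the calls were kept, and with length and GC offsets 71.3%.

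Called neighbours, 5 in the main window, numbered 5 to 7 with 1 library left out. They numbered 8 among protein-coding genes alone, in DESeq2, with quantile normalization and with length and GC offsets, and 9 in limma on FPKM with no filter, from 0.1 or with array weights. They numbered 10 with total counts, 13 on the TPM scale, 1 within 100 kb and 15 within 1 Mb. Gene lists past the threshold, 13, numbered 12 to 16 with 1 library left out. They numbered 0 with an estimated correlation, 29 in fry and 45 in its mixed test, 23 in limma on FPKM with no filter, and 10 with length and GC offsets. For glycolysis camera's direction went from up to down (median -0.0080 before, -0.22 with no FPKM filter, -0.20 with quantile normalization, adjusted p = 0.0244 and 0.0205). Medians of NF-kB genes (-0.027), cytosolic ribosomal proteins (-0.18) and translation factors (-0.30) lay below 0 on the TPM scale with camera's direction up. Directions turned for cytosolic ribosomal proteins (-0.065), translation factors (-0.11) and RPS24 (-0.00033) with quantile normalization. They turned for mitochondrially encoded genes (-0.63 with quantile normalization, -0.37 with offsets, -0.39 with offsets and block), and on the TPM scale RPS24 (-0.12), RPL21 (-0.055), RPL24 (-0.012) and EZH2 (-0.0072). Of the other named genes and lists, 3422 values stayed on their side of the threshold, 134 lost the call and 81 gained it. Gene and list values under the 0.01 threshold and the 2-fold minimum repeat the main fit, so they stayed by construction. Both settings also count among the alternatives given for single lists.

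Replicate numbers did not pair the libraries: correlations of same-numbered deviations were -0.070, -0.012 and -0.030, and no library correlated best with its own number. With the replicate block, calls numbered 2114 higher and 2315 lower, RPLP0P2 was at -0.20, 12 lists passed and YAP/TAZ targets lost the call (adjusted p = 0.0520). With length and GC offsets and the replicate block, 1879 genes were lower and 3 neighbours passed. Depth did not limit RPLP0P2, which had 1840 to 3682 counts.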

Other observations

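The tests of poly(A) selection, of RPLP0 reads, of KEGG pathways, of length and GC offsets and of ribosomal DNA counts were chosen only after the data were seen. Of 296 KEGG pathways, taken from the annotation in the deposited table and holding 10 to 300 tested genes, 44 passed camera, 15 up and 29 down, and 0 passed with an estimated correlation. Aminoacyl-tRNA biosynthesis genes were higher in 22 of 44 members and lower in 6 (median log2 fold change 0.28, adjusted p = 0.0133). Protein export genes were higher in 12 of 23 and lower in 1 (median 0.28, adjusted p = 0.0133). Genes of glycine, serine and threonine metabolism were higher in 9 of 27 and lower in 2 (median 0.31, adjusted p = 0.0259). ABC transporters were lower in 12 of 25 members and higher in 0 (median -0.61, adjusted p = 0.00204). Hedgehog pathway genes, to which GLI1 belongs, were lower in 12 of 34 and higher in 1 (median -0.29, adjusted p = 0.0264). Steroid biosynthesis was lower in 8 of 17 members and higher in 0 (median -0.50, adjusted p = 0.000232). With an estimated correlation each of these 6 had an adjusted p = 0.416. With length and GC offsets 8 pathways kept direction and call, among them aminoacyl-tRNA biosynthesis (adjusted p = 0.0234) and steroid biosynthesis (1.92e-05). So did oxidative phosphorylation (0.00484) and the ribosome pathway of 130 tested genes (0.0315), whose median went from 0.36 to 0.15. The smaller list of cytosolic ribosomal proteins lost its call with these offsets (0.179). ABC transporters (0.192), Hedgehog (0.663), protein export (0.183) and glycine, serine and threonine metabolism (0.0831) lost their calls with the offsets. The Wnt signaling pathway was lower in 36 of 102 members and higher in 12 (median -0.26, adjusted p = 0.0217), unlike the list of WNT targets, which did not pass. With an estimated correlation it had an adjusted p = 0.418, and with the offsets 0.443.

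Short transcripts were higher and long ones lower in the knockdown. Protein-coding genes, 10854 of them, were ranked by their longest annotated transcript into 5 equal parts. The part with the shortest transcripts, 192 to 2182 bases, had a median log2 fold change of 0.31, with 866 genes higher and 184 lower. The part from 5984 bases up had -0.20, with 246 higher and 758 lower. Ranked by GC content of the transcript, the medians were 0.10 in the lowest of the 5 parts and -0.26 in the highest. Processed pseudogenes, 1214 of them tested, were higher in 102 cases and lower in 20.

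Gene lists could follow this trend rather than a change of their own. The bootstrap SE values here and in the next paragraph come from redrawing the members of a list, with the libraries fixed. They treat members as independent, though members can vary together, and they hold no spread between libraries. After each library's trend with length and GC content was removed, some lists kept over 0.5 of their median beyond its SE and stayed past the threshold. These were ATF4 and amino acid response (0.95, bootstrap SE 0.16), proteasome (0.44, SE 0.11), G2/M and mitosis (0.46, SE 0.08), heat shock (-0.61, SE 0.12) and cholesterol genes (-0.54, SE 0.17). That argues against the trend, as fitted, being their whole cause. The fit used each gene's longest annotated transcript, which need not be the one expressed, so part of the trend may remain. With an estimated correlation G2/M (adjusted p = 0.0568), cholesterol (0.0568) and heat shock genes (0.112) did not pass with the offsets. Cytosolic ribosomal proteins went from 0.34 (SE 0.03) to 0.077 (SE 0.05), the Notch pathway from -0.74 (SE 0.38) to -0.31 (SE 0.27) and YAP/TAZ targets from -0.28 (SE 0.19) to -0.011 (SE 0.14). They shrank by over 2 bootstrap SE of the change (0.05, 0.15 and 0.09) to less than 0.5 of their size. Their calls were lost too, which the trend as a cause would give. However, Notch and YAP/TAZ also lost calls where the median moved little. Relative to the median of all genes, Notch was at -0.74 with total counts, as in the main fit, and at -0.67 in limma on FPKM. The YAP/TAZ median itself was -0.28 with the replicate block. Respiratory chain genes (0.51 to 0.25, SE 0.06), chromatin enzymes (-0.25 to -0.16, SE 0.10), NF-kB genes (0.50 to 0.42, SE 0.23) and translation factors (0.22 to 0.10, SE 0.08) met neither criterion, so a share of the trend and a change of their own cannot be told apart. A response to the knockdown, which the design names, stays open and untested for each list, as does a difference between library preparations, since the labels give no batches.

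The rise of counts at the ribosomal DNA repeats and of other non-polyadenylated RNAs could come from less complete poly(A) selection of the knockdown libraries or from a change of these RNAs in the cells. Replication-dependent histone mRNAs, which lack a poly(A) tail, had a median log2 fold change of 0.27 (bootstrap SE 0.20), below the 1 that the first explanation was taken to need, and 51 small nucleolar RNAs had -0.31 with 0 higher and 2 lower, while 10 small nuclear and 4 small Cajal body RNAs had 0.73 and 0.93. Their low control levels, at medians of 0.989, 0.393, 0.203 and 0.165 CPM, leave room for polyadenylated forms or reads of host genes that would hide a rise, so the explanations cannot be told apart, and all 3 knockdown libraries share the difference. Counts taken up by the ribosomal DNA genes lower all other genes alike on the total-count scale, and 22.4% of the calls there were higher (1443 genes), which argues against them as the whole cause of the gene calls. Leaving these genes out tests little, since TMM already discounts them, and their part in the lower calls on the total-count scale stays open.

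The small difference of RPLP0P2 could come from reads of RPLP0 that were counted at the pseudogene, or from a weak knockdown. With each library's trend with length and GC content removed, its log2 fold change in edgeR was -0.082 (adjusted p = 0.426) instead of -0.20. That offset took the longest annotated transcript, which has an exon of 2865 bases, while the retrocopy transcript has 961 bases. The value therefore depends on the transcript chosen. A share of the length and GC trend in the difference stays open. Within groups, log2 RPLP0P2 had a slope of -0.087 (SE 0.15) on log2 RPLP0 over the 6 libraries, and -0.87 (SE 0.16) without knockdown replicate 1, and the matching slopes of RPLP0P6 were 0.61 (SE 0.18) and 1.49 (SE 0.27). RPLP0 hardly varied among the controls (log2 SD 0.013), so the slope rests on knockdown libraries that may differ in knockdown too, and reads of RPLP0 and a weak knockdown cannot be told apart. The larger difference in FPKM than in CPM is in line with ribosomal DNA counts in the per-million total: without these 4 genes in the total, RPLP0P2 in CPM differed by -19.3% between the groups, against -26.5% with them and -13.1% with TMM, which closes 54.0% of the gap. Hairpins that act without lowering the RNA, and a true fall of 13.1% stay open and untested. The counts pool transcripts with and without the retrocopy, so this fall is that of the gene as a whole, not of any single transcript.

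The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05, and in 1 of the 10 splits, the real one, each count was as large as observed. Genes past the threshold numbered 5688 in the real split and at most 1 in the others, and called neighbours of RPLP0P2 5 and at most 0. Each other split puts libraries of both groups on each side, so the group difference adds to the spread within sides. Few gene calls can follow there. Gene lists numbered 13 in the real split and 4 to 11 in the others, where hardly any gene passed. These splits still hold part of the group difference, so they do not give the number of lists without one.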
